A study of Mus musculus with 7 samples.

How the data were processed

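RNA abundance was measured on 7 Affymetrix mouse arrays: 2 of dissected basal cell carcinoma, 2 of newborn (P0) epidermis and 3 of the PDKC1 carcinoma cell line at 0 h, 6 h and 10 h of cyclopamine. Per the labels' protocols, total RNA was extracted with a column kit and biotinylated cRNA was made by the standard Affymetrix method from 100 ng of RNA for each tissue array and 2000 ng for each PDKC1 array. The dose and vehicle of cyclopamine and the software that summarised probes are not given in the sources used here.

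The deposited table holds a linear signal intensity per probe set, as made by the authors. The mean of each array after leaving out the lowest and highest 2 percent of its probe sets lay within 1 unit of 500, which scaling of each array as a whole would give, although the sources do not state the procedure; quantiles still differed between arrays, and no other normalization was visible. No further normalization was applied. No 2 arrays had identical values. The number of arrays limits the precision.

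The table held 45101 probe sets. The 64 control probe sets, 932 probe sets assigned to several genes and 9160 without a gene name were left out of gene-level tests. The remaining 34945 represented 18193 genes, of which 9010 had several probe sets; the probe set with the highest mean log2 value over the 7 arrays stood for its gene. Symbols were updated through Entrez identifiers, and a list symbol was resolved through a synonym only where it was not itself a current symbol. Of 488 entries in the gene lists 445 were measured; the others were not analysed here. Intensities were taken as log2(intensity + 16), where 16 is the 20th percentile of the tissue arrays rounded to a power of 2.

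Tumour and epidermis were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend) on the 4 tissue arrays, with Benjamini-Hochberg adjustment over all 18193 genes and calls at an adjusted p under 0.05. No covariate or block was used, since no label ties the replicate numbers across tissues. The 37 gene lists were tested with limma's camera (preset correlation 0.01), adjusted over the 37 lists, beside camera with an estimated correlation and fry. fry tests whether a list's genes move, on balance, in 1 direction, and does not compare the list with other genes. All tests were two-sided. The lists covered Hedgehog components and targets, epidermal layers and barrier lipids, hair follicle, hair shaft and sebaceous gland, Wnt, Notch, p53, BCL2, mitosis and DNA replication genes. They also covered markers of fibroblasts, endothelium, macrophages, T and NK cells, B and plasma cells, MHC class II and Langerhans cells, mast cells, neutrophils, melanocytes, skeletal muscle, adipocytes, erythroid cells and Schwann cells. The remaining lists were interferon, wound, cholesterol, hypoxia, unfolded protein response, immediate early, mesenchymal, imprinted and ribosomal genes.

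In PDKC1, with 1 array per time, genes at least 2-fold from 0 h in the same direction at 6 h and 10 h were counted among genes whose brightest array was over its median probe set, without a test. Genes that set the 6 h or the 10 h array apart from the other 2 were counted in the same way. The median of each list was placed among 10000 random lists of the same size matched on mean level in 20 bins. The overlap of tumour-higher genes with genes lower after cyclopamine was set beside the number expected from independent lists and 10000 random sets matched on level.

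The genes named were chosen by rule: the 12 largest differences in each direction among called genes whose groups did not overlap, every measured Hedgehog component, and up to 4 called members of each list by size of difference, or up to 2 of the brightest where none was called. For PDKC1 they were the 10 largest falls and rises at both times, the Hedgehog targets, and up to 4 members of a list beyond the percentiles 2.5 or 97.5 at both times; for the overlap, up to 12 genes. Exceptions are stated where they occur. The groups, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, apart from those stated as chosen later.

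Alternatives changed 1 choice at a time: quantile normalization, centring each array on its median, a pseudocount of 4 or 64, leaving out genes under the 40th percentile of mean level, the mean of all probe sets of a gene, all probe sets, no variance trend, a replicate block, leaving out each tissue array, at least 2-fold calls, and all 7 arrays in 1 fit. For PDKC1 they also included 1.5-fold differences and no filter on level. A filter at the 75th percentile of intensity was added after the data were seen. The fit was tested on simulated data with 50 genes changed at each of 4 sizes: 0 were called at 2-fold, 23 at 4-fold, 41 at 8-fold and 47 at 16-fold, with 6 false calls and 0 of the wrong sign. Far fewer genes were changed than were called in the data, so these shares do not carry over to the data. The ratios of 3' to 5' control probe sets for Actb and Gapdh were computed on each array from the deposited intensities.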

Results

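Gene expression was measured in mouse basal cell carcinoma with single-channel Affymetrix arrays of 45101 probe sets. The 7 arrays comprised 2 arrays of dissected basal cell carcinoma, 2 arrays of normal epidermis from newborn (P0) mice, and 3 arrays of PDKC1, a mouse basal cell carcinoma cell line. The PDKC1 arrays held untreated cells (0 h) and cells after 6 h and 10 h with cyclopamine, a plant alkaloid that blocks the Hedgehog pathway at Smoothened. Values were signal intensities, and the small number of arrays limits the precision. Nothing in the labels says whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

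The RNA of the tumours differed from that of the epidermis in its 5' signal. The Actb control probe sets gave a 3' to 5' intensity ratio of 11.3 in tumour 1 and 93.1 in tumour 2, against 3.98 and 2.84 in the epidermis arrays. For Gapdh the ratios were 10.6 and 15.4 in the tumours and 5.27 and 4.52 in the epidermis. In PDKC1 they were 1.15, 1.18 and 1.21 for Actb and 0.726, 0.741 and 0.699 for Gapdh at 0 h, 6 h and 10 h. The median probe set had an intensity of 118.2 and 127.9 in the tumours and 71.0 and 75.3 in the epidermis. Spearman's rho over probe sets, which are not independent replicates, was 0.920 between the tumours, 0.898 between the epidermis arrays and 0.733 to 0.801 between tissues.

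**Figure D1:**
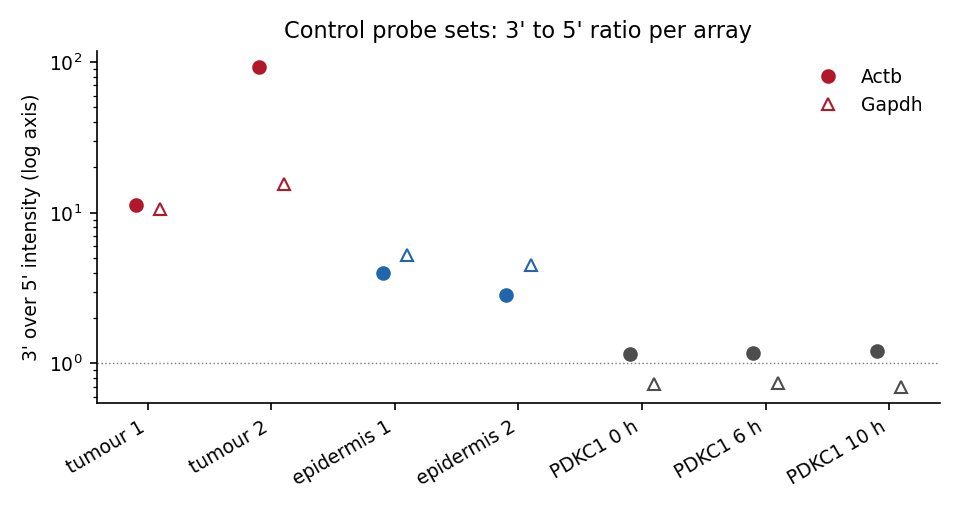
Ratio of 3' to 5' intensity of the Actb (circles) and Gapdh (triangles) control probe sets on each of the 7 arrays, on a log axis. Tumour 2 had the highest Actb ratio, 93.1, and the PDKC1 arrays lay near 1.15 for Actb.

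The comparison of tumour with newborn epidermis asked which genes differ between the carcinoma and normal skin epithelium. Every epidermis array was from newborn mice, so a difference from the tumours may reflect age as well as carcinoma. This limit holds for every gene and list of the comparison. Genes of Hedgehog signalling, the pathway whose activation drives basal cell carcinoma, were higher in the tumours. Of 14 measured components 9 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median log2 difference, tumour minus epidermis, of 1.47 (adjusted p = 0.00156 by camera; adjusted p = 0.424 with an estimated correlation). Hhip, a decoy receptor induced by the pathway, had a mean intensity of 5740.4 in tumour and 32.4 in epidermis, a log2 difference of 6.89 ± 0.42 (SE, 2 arrays per group; adjusted p = 0.000436), which was 7.35 with a pseudocount of 4 and 5.86 with 64. Gli1, a transcription factor and direct target of the pathway, had 2063 against 242 (3.04 ± 0.28, adjusted p = 0.000953). The receptor gene Ptch1 was bright in both tissues, at 32665 and 11878 (1.43 ± 0.27, adjusted p = 0.00893). Gli2 differed by 2.12 ± 0.20, Gli3 by 1.52 ± 0.24, the signal transducer Smo by 1.67 ± 0.20 and the co-receptor genes Boc and Cdon by 3.41 ± 0.35 and 1.37 ± 0.32. Kif7, a kinesin that regulates the GLI proteins, differed by 1.57 ± 0.36. Shh, the ligand, was the component that was lower, at 276 in tumour and 4637 in epidermis (-4.02 ± 0.32, adjusted p = 0.000713). Sufu (0.63, adjusted p = 0.144), Gas1 (0.38, 0.248), Disp1 (0.16, 0.779) and Hhat (0.87, 0.329) were not called. Of 16 Hedgehog target genes 8 were higher and 1 lower (the same counts adjusted over the list alone; median 1.09, adjusted p = 0.00409; adjusted p = 0.424 with an estimated correlation). Mycn, a proliferation-promoting transcription factor, differed by 2.62 ± 0.20. The receptor gene Pdgfra differed by 3.51 ± 0.49, but it is also a fibroblast marker, and 14 of 16 fibroblast and matrix genes were higher. Its intensity was 6.90 in PDKC1 cells at 0 h, so its rise need not come from carcinoma cells. Hhip and Boc were at 239.6 and 180.1 there, also far under their tumour means of 5740.4 and 1794, so the same holds for them. Gli3, in contrast, was at 1358 there and 1149 in tumour. Which cells hold the rise was not tested for any component.

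Several of these calls rested on a setting or an array. With each array centred on its median the medians were 0.83 for components (6 higher) and 0.45 for targets (5 higher), and with quantile normalization 1.32 (9) and 0.79 (7). With the mean of all probe sets of a gene, Mycn differed by 0.38 (adjusted p = 0.527), Cdon had adjusted p = 0.455, and Gli3 0.0552. With each array centred on its median, Ptch1 (0.0551), Cdon (0.111) and Kif7 (0.104) were not called; with quantile normalization Kif7 was not (0.0890), and without a variance trend Cdon was not (0.0674). With epidermis array 1 left out, 4 components and 5 targets were called higher, against 5 and 5 without array 2. The adjusted p without epidermis array 1 was 0.114 for Ptch1, 0.0530 for Smo, 0.0854 for Gli3, 0.172 for Cdon and 0.131 for Kif7. Without epidermis array 2 it was 0.0984 for Ptch1, 0.0617 for Gli3, 0.104 for Cdon and 0.120 for Kif7. Hhat was called without tumour 1 (adjusted p = 0.0474), and Gas1 was called without tumour 2 (0.0438), with quantile normalization (0.0246) and with the mean of probe sets (0.00946).

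**Figure D2:**
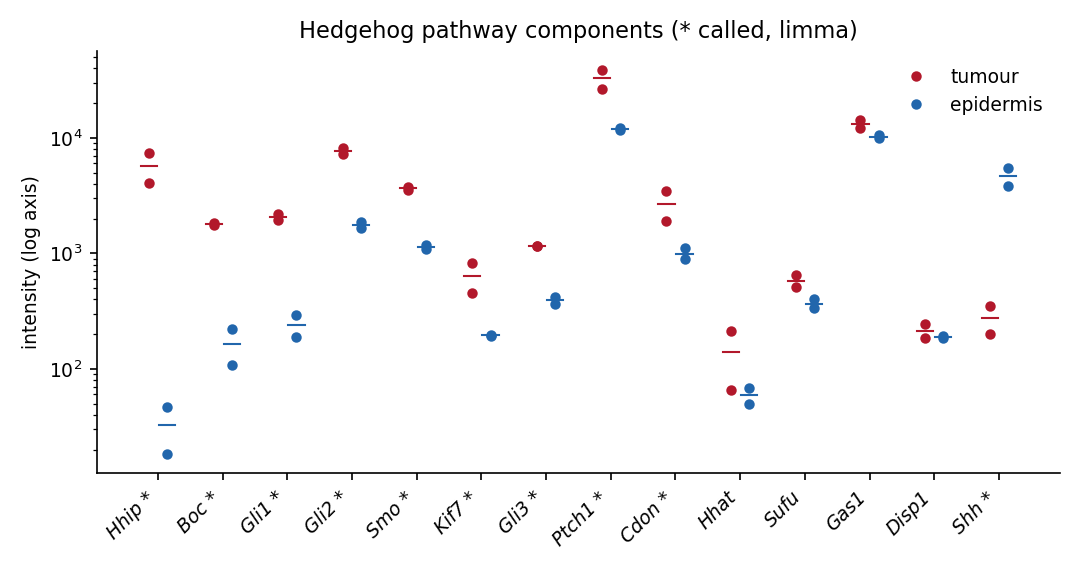
Intensity of the 14 measured Hedgehog components on each tumour and epidermis array (points) with the group mean (bar), on a log axis; an asterisk marks a component called different. Hhip, Boc and Gli1 were higher in tumour and Shh was lower.

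Genes of the upper epidermal layers were lower in the tumours. All 15 called members of 16 granular layer and cornified envelope genes were lower (16 adjusted over the list alone), with a median of -3.56 (adjusted p = 6.73e-10; adjusted p = 0.424 with an estimated correlation). The envelope precursor gene Ivl differed by -5.70 ± 0.24 (adjusted p = 0.000245), the corneodesmosome gene Cdsn by -5.41 ± 0.45, the protease gene Klk5 by -5.19 ± 0.34 and the crosslinking enzyme gene Tgm1 by -5.08 ± 0.55. Of 13 genes of barrier lipid synthesis 10 were lower (11 adjusted over the list alone; median -3.22, adjusted p = 2.82e-07; adjusted p = 0.424 with an estimated correlation). They included the lipoxygenase gene Alox12b (-5.81 ± 0.48, adjusted p = 0.000752), Pnpla1 (-4.95 ± 0.26), which acts in acylceramide synthesis, and the ceramide synthase gene Cers3 (-3.71 ± 0.24). Of 8 spinous layer markers 7 were lower (8 adjusted over the list alone; median -1.97, adjusted p = 0.000260; adjusted p = 0.424 with an estimated correlation), among them the keratin gene Krt1 (-2.48 ± 0.23, adjusted p = 0.000947) and Krtdap (-2.98 ± 0.58). With quantile normalization and with each array centred on its median, the medians were -3.39 and -4.20 for granular, -3.19 and -3.86 for barrier lipid, and -1.52 and -2.61 for spinous genes. These groups also differed between the tumours. From tumour 1 to tumour 2, the array with the higher Actb ratio, the median of their members changed by -1.35 for granular, -0.50 for barrier lipid and -0.82 for spinous genes. With 2 tumours this cannot be tied to RNA quality rather than to what each tumour held. Without tumour 2 the granular median was -2.94 and 16 genes were lower. Without epidermis array 1, 9 granular, 8 barrier lipid and 1 spinous genes were called lower, against 10, 9 and 1 without array 2; Krtdap was not among them (adjusted p = 0.0707 and 0.0675).

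Basal keratinocyte markers, which the proliferating layer of the epidermis expresses, were not called as a list. Of 13 markers 1 was lower, and 0 were called adjusted over the list alone by limma, with 1 higher and 1 lower at an unadjusted p under 0.05. The list's median was 0.14, while camera's direction was down (adjusted p = 0.974), and centring each array on its median turned the list's median to -0.50, as did leaving out tumour 1 (-0.10). The counts turned too: 4 were higher and 1 lower without tumour 2 (median 0.26), 1 was higher with quantile normalization (0.33), and 3 were lower with centring. The called member was Krt14 (-1.34 ± 0.35, adjusted p = 0.0309), which was not called with quantile normalization (0.210), with the mean of probe sets (0.176), without a variance trend (0.0797), or without epidermis array 1 (0.130) or 2 (0.207).

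Markers of the hair follicle moved apart by compartment. Of 14 markers of follicle epithelium and its stem cells 11 were higher (11 higher and 1 lower adjusted over the list alone; median 2.23, adjusted p = 0.000481; adjusted p = 0.438 with an estimated correlation). Tbx1 differed by 4.52 ± 0.26 (adjusted p = 0.000432), the stem cell marker Lgr5 by 3.78 ± 0.34 (adjusted p = 0.000877) and the stem cell transcription factor gene Lhx2 by 2.59 ± 0.26. Of 18 hair shaft and inner root sheath genes 9 were lower and 1 was higher, Hoxc13, named after its values were seen (10 and 1 adjusted over the list alone; median -1.64, adjusted p = 0.00198; adjusted p = 0.438 with an estimated correlation). With tumour 1 left out its median was -0.87, with 2 higher and 10 lower (adjusted p = 0.0345). The keratin genes Krt35 (-3.07 ± 0.89) and Krt71 (-2.80 ± 0.75) were among the lower members, and both were not called without epidermis array 1 (adjusted p = 0.117 and 0.104), without array 2 (0.196 and 0.170) or without a variance trend (0.0941 and 0.0764). Of 6 sebaceous gland markers 2 were higher (3 adjusted over the list alone), and the list was not called (median 0.93, adjusted p = 0.158; 0.50 without tumour 1, 0.41 with quantile normalization and 0.29 with centring) except without tumour 2 (1.78, 0.00790). Follicle epithelium had a median of 2.08 with quantile normalization and 1.59 with centring (8 higher and 1 lower with each), and the hair shaft list -2.17 and -2.28. Scd1, a fatty acid desaturase gene, differed by 2.70 ± 0.27. Without epidermis array 1, 9 follicle epithelium genes were called higher, against 8 without array 2, and at most 1 hair shaft gene was called lower without either.

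Markers of fibroblasts, endothelium and mast cells, mesenchymal transition factors and MHC class II genes were higher in the tumours. Of 16 fibroblast and matrix genes 14 were higher (15 adjusted over the list alone; median 2.35, adjusted p = 1.16e-06; adjusted p = 0.424 with an estimated correlation). Pdgfrb, a receptor of mesenchymal cells, differed by 4.68 ± 0.32 (adjusted p = 0.000467), the collagen gene Col1a1 by 4.19 ± 0.37 (adjusted p = 0.000903) and Thy1 by 3.35 ± 0.28. Of 11 mesenchymal transition factors 7 were higher (8 adjusted over the list alone; median 1.77, adjusted p = 0.000596; adjusted p = 0.438 with an estimated correlation), among them Prrx1 (3.32 ± 0.27) and Zeb2 (3.18 ± 0.32). Of 12 endothelial markers 5 were higher (7 adjusted over the list alone; median 1.32, adjusted p = 0.00335; adjusted p = 0.424 with an estimated correlation), including Vwf (3.04 ± 0.43), the von Willebrand factor gene. Of 8 mast cell markers 5 were higher (the same adjusted over the list alone; median 2.19, adjusted p = 0.00310; adjusted p = 0.424 with an estimated correlation), including Hdc (4.69 ± 0.49), which makes histamine, and the IgE receptor gene Ms4a2 (4.38 ± 0.33). Of 7 MHC class II and Langerhans cell genes 4 were higher (the same adjusted over the list alone; median 2.85, adjusted p = 0.00310; adjusted p = 0.511 with an estimated correlation), and H2-Aa differed by 5.08 ± 0.23 (adjusted p = 0.000288). The mesenchymal list had a median intensity of 540.6 in PDKC1 at 0 h, against 727.4 and 852.8 in the tumours. Its rise therefore need not come from connective tissue. Scaling moved the lists of this paragraph. With quantile normalization the medians were 2.45 for fibroblast (12 higher), 1.56 for mesenchymal (7), 0.60 for endothelial (2), 1.71 for mast cell (4) and 2.38 for MHC class II genes (4). With each array centred on its median they were 1.71 (11), 1.13 (5), 0.67 (2), 1.55 (4) and 2.21 (4) in the same order. The mesenchymal median was 0.72 with the mean of probe sets (5 higher) and 1.12 with a pseudocount of 64, where the endothelial median was 0.79. Epidermis levels of Hdc lay under the pseudocount of 16, so its difference was 3.37 with a pseudocount of 64. With epidermis array 1 left out, 10 fibroblast, 4 mesenchymal, 1 endothelial, 3 mast cell and 4 MHC class II genes were called higher, against 9, 4, 2, 2 and 4 without array 2.

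Skeletal muscle markers differed between the tumours. Of 13 markers 3 were higher than in epidermis (the same adjusted over the list alone; median 1.56, adjusted p = 0.0397; adjusted p = 0.753 with an estimated correlation). Their median changed by -3.03 from tumour 1 to tumour 2, and without tumour 1 the list was not called (median 0.38, adjusted p = 0.547), while without tumour 2, 11 markers were higher (median 2.81). Its median was 0.99 with quantile normalization and 0.92 with each array centred on its median. The list was also not called with a pseudocount of 4 (adjusted p = 0.0532) or with dim genes left out (0.215). The muscle myosin gene Myh1 was at 6768 in tumour 1 and 2271 in tumour 2 against a mean of 4.75 in epidermis (7.58 ± 0.53, adjusted p = 0.000515). The epidermis lay under the pseudocount of 16, which sets the size of this difference: for gene Myh1 it was 5.86 with a pseudocount of 64 and 8.88 with 4. Myh2 differed by 3.60 ± 0.46, and by 2.13 with a pseudocount of 64.

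Markers of other cell types were not called as lists by camera, while fry called the Schwann cell list (adjusted p = 0.0429). Of 6 Schwann cell markers 4 were higher and 1 lower (the same adjusted over the list alone; median 2.46, adjusted p = 0.0934), with Egfl8 at 3.47 ± 0.44 (2.07 with a pseudocount of 64, its epidermis level being under 16); the list was called with each array centred on its median (adjusted p = 0.0181), with the mean of probe sets (0.00628), and without epidermis array 1 (0.0431) or 2 (0.0490). Macrophage markers had a median of -0.14 with 2 of 12 higher and 1 lower (adjusted p = 0.838). Melanocyte markers had 0.08 with 2 of 11 higher, Tyrp1 (2.76 ± 0.24) being one, and 1 lower (0.942). For adipocyte markers the values were 1.18 with 2 of 5 higher (0.264); the median was 1.89 with 3 higher without tumour 2 and 0.81 without tumour 1, and limma called none without tumour 1 or either epidermis array. Erythroid markers had 0.34 with 1 of 5 higher and 1 lower (0.843). The median of 7 B and plasma cell markers was 0.61 although camera's direction was down (adjusted p = 0.974), and Blnk alone was called (-1.93 ± 0.25; adjusted p = 0.0652 without epidermis array 1). By limma 0 of 11 T and NK cell markers (median 0.66, adjusted p = 0.607) and 0 of 7 neutrophil markers (-0.27, 0.452) were called, and 0 of either had an unadjusted p under 0.05. Several of these medians turned with the setting. With each array centred on its median they were 0.54 for adipocyte (0 higher, 1 lower), -0.91 for neutrophil, 1.82 for Schwann cell, -0.78 for macrophage (0 higher, 4 lower), -0.56 for melanocyte (1 higher, 4 lower), -0.30 for erythroid, -0.03 for B and plasma cell and 0.02 for T and NK cell markers. With quantile normalization they were 0.77 (0 higher), -0.97, 1.89, -0.67, -0.29, 0.01, 0.12 and 0.26 in the same order. Melanocyte markers had -0.14 without tumour 1 and -0.01 without epidermis array 1, where erythroid markers had -0.03 and B and plasma cell markers -0.26; without tumour 2, macrophage markers had 0.20, T and NK cell markers 0.04 and B and plasma cell markers 0.17. With dim genes left out the medians were 0.09 for macrophage, -0.43 for T and NK cell and -0.56 for B and plasma cell markers. The counts adjusted over each list alone were the same as over all genes for the 8 lists of this group.

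Lists of early response, stress, growth and synthesis genes were called lower in the tumours. Of 15 immediate early genes 9 were lower (10 lower and 1 higher adjusted over the list alone; median -1.92, adjusted p = 0.000260; adjusted p = 0.571 with an estimated correlation), including Fos (-2.75 ± 0.24, adjusted p = 0.000793) and the mRNA decay factor gene Zfp36 (-3.16 ± 0.38). Of 14 genes of the unfolded protein response and ATF4 7 were lower (7 lower and 1 higher adjusted over the list alone; median -1.13, adjusted p = 0.00156; adjusted p = 0.424 with an estimated correlation), including Chac1 (-3.86 ± 0.27) and Trib3 (-3.03 ± 0.28). Of 13 imprinted and fetal growth genes 4 were lower and 3 higher (7 and 3 adjusted over the list alone; median -1.18, adjusted p = 0.0163; adjusted p = 0.571 with an estimated correlation). The growth factor gene Igf2 differed by -5.04 ± 0.32 (adjusted p = 0.000463), while the imprinted noncoding RNA Meg3 differed by 3.99 ± 0.27. The imprinted list was not called with each array centred on its median (0.111) or with dim genes left out (0.0903). Of 18 cholesterol synthesis genes 8 were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.80, adjusted p = 0.00276; adjusted p = 0.615 with an estimated correlation; 0.125 with quantile normalization), and Mvk, mevalonate kinase, differed by -2.21 ± 0.29. Of 9 ribosomal protein genes 6 were lower (the same adjusted over the list alone; median -0.99, adjusted p = 0.00312; adjusted p = 0.424 with an estimated correlation), and with quantile normalization the list was not called (median -0.43, adjusted p = 0.410). With quantile normalization the medians were -2.19 for immediate early (9 lower), -1.36 for unfolded protein response (8), -1.48 for imprinted (7 lower, 3 higher) and -0.59 for cholesterol genes (7 lower, 1 higher). With centring they were -2.56 (11), -1.77 (10), -1.82 (9 and 2) and -1.44 (11 and 0), and -1.63 for ribosomal genes (8). The unfolded protein response median was -0.66 with the mean of probe sets, and the imprinted median -0.61 with a pseudocount of 64. These lists also differed between the tumours, which with 2 tumours cannot be tied to RNA quality. From tumour 1 to tumour 2 members changed by a median of -0.78 for immediate early and -0.25 for unfolded protein response genes. The changes were -0.62 for cholesterol, -0.45 for ribosomal and 0.29 for imprinted genes. Without tumour 1, which leaves the tumour with the Actb ratio of 93.1, the medians were -2.43 for immediate early, -1.28 for unfolded protein response, -1.19 for cholesterol (12 lower) and -1.21 for ribosomal genes. Without tumour 2 they were -1.48, -0.92, -0.57 (10 lower) and -0.76, while the imprinted list had -1.08 and -1.02. With epidermis array 1 left out, 5 immediate early, 2 unfolded protein response, 3 imprinted and 2 cholesterol genes were called lower, against 5, 2, 3 and 3 without array 2, and at most 1 ribosomal gene was called without either.

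Cell cycle and signalling lists were not called by camera. By fry, p53 targets (adjusted p = 0.0427) and the BCL2 family (0.0489) were called. Mitosis genes had a median of -0.37, with 3 of 19 lower over all genes (adjusted p = 0.0922). By limma 0 of them were called adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05. This list was called lower with quantile normalization (adjusted p = 0.0378), without tumour 2 (-0.70, 0.00546) and without epidermis array 1 (-0.74, 0.00786), while the median was -0.16 without tumour 1 (0.827) and -0.11 without epidermis array 2 (0.489). DNA replication genes had -0.25 (1 of 18 higher, 4 lower; adjusted p = 0.153), and were called lower with the mean of probe sets (0.0246) and without tumour 2 (-0.52, 0.0211). Their median was 0.09 without tumour 1, with 3 higher and 4 lower (adjusted p = 0.710), -0.03 without epidermis array 2 (0.495) and -0.38 without array 1 (0.0507). Hypoxia and glycolysis genes had -0.37 (1 of 14 higher, 5 lower; adjusted p = 0.0709), and were called lower with the mean of probe sets (0.00298), without tumour 2 (0.0469) and without epidermis array 2 (0.0299). Egln3, a prolyl hydroxylase gene induced by hypoxia, differed by -3.48 ± 0.22. Targets of p53 had -0.18 (2 of 14 higher, 5 lower; adjusted p = 0.185), including the cell cycle inhibitor gene Cdkn1a (-2.39 ± 0.32). The BCL2 family, which controls apoptosis, had -0.07 (2 of 11 higher, 2 lower; 0.563), the Notch pathway -0.03 (1 of 12 higher, 2 lower; 0.800) and Wnt targets -0.40 (2 of 14 higher, 1 lower; 0.609). The Wnt inhibitor gene Wif1 differed by 4.04 ± 0.51 and the Notch target Hes5 was at 8.80 in tumour, under the pseudocount of 16, and 142 in epidermis, a difference of -2.62 that was -1.47 with a pseudocount of 64 and -3.45 with 4 (adjusted p = 0.0638 without epidermis array 2). Interferon-stimulated genes had 0.09 (1 of 12 higher, 1 lower; 0.843), and Irf7 differed by -3.74 ± 0.26. Their median was -0.47 with quantile normalization (0 higher, 1 lower), -0.55 with each array centred on its median (0 higher, 1 lower) and -0.05 without epidermis array 2. The Notch median was -0.61 with quantile normalization, -0.67 with centring (1 higher, 4 lower), -0.29 without tumour 1, 0.07 without tumour 2, 0.07 with the mean of probe sets and 0.10 with dim genes left out. With centring the medians were -0.82 for p53 (0 higher, 6 lower), -0.71 for BCL2 (1 and 4), -1.04 for Wnt (2 and 4), -1.02 for hypoxia (1 and 9), -1.01 for mitosis (7 lower) and -0.90 for DNA replication genes (7 lower). With quantile normalization they were -0.63, -0.71, -0.65, -0.27, -0.87 and -0.47 in the same order. The Wnt median was -0.16 without tumour 2, -0.14 without epidermis array 2 and -0.12 with dim genes left out, and the BCL2 median was -0.17 without tumour 2. Wound keratins and inflammatory mediators had 1.54 (7 of 13 higher, 3 lower; 0.286; 0.0359 with each array centred on its median, where the median was 0.90 with 4 higher and 4 lower; 1.04 with quantile normalization), with S100a8, a subunit of calprotectin, at 5.63 ± 0.54. Adjusted over the list alone, the Notch pathway had 2 higher and 2 lower, hypoxia genes 1 and 6; for DNA replication, p53, BCL2, Wnt, interferon and wound genes these counts were as over all genes.

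**Figure D3:**
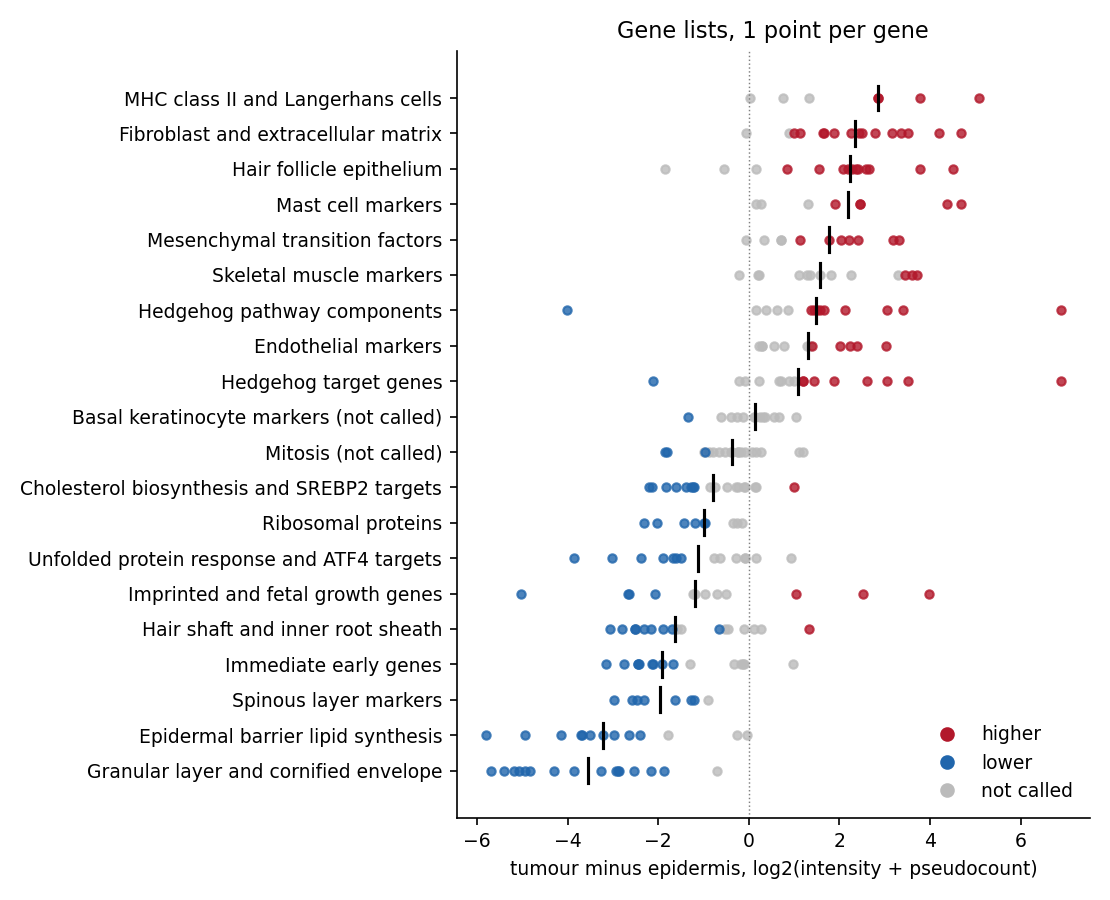
Log2 difference, tumour minus epidermis, of each measured gene (points) in the 18 gene lists called by camera and in the basal keratinocyte and mitosis lists, which were not called; a black tick marks each median. The granular layer median was -3.56 and the fibroblast median 2.35; the basal list's median changed sign with each array centred on its median.

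Single genes with the largest differences came from many functions. Among the 12 largest rises at a pseudocount of 16 were, besides Myh1 and Hhip, Defb6, a beta-defensin gene, at 6126 in tumour and 55.6 in epidermis (6.42 ± 0.24, adjusted p = 0.000245), the carbonic anhydrase gene Car3 (6.35 ± 0.38), the angiogenin gene Ang (6.29 ± 0.44) and the cell adhesion gene Nrcam (6.13 ± 0.26). Krt2, a keratin of the upper epidermis, was at 18385 in tumour 1 and 233.7 in tumour 2 (5.81 ± 1.71, adjusted p = 0.0441). It was not called with quantile normalization (adjusted p = 0.0917), with each array centred on its median (0.0569), a pseudocount of 64 (0.0765), the mean of probe sets (0.0537), no variance trend (0.0977), or without epidermis array 1 (0.144) or 2 (0.156). The lower genes were led by Lce1m, a cornified envelope gene, at 2244 in tumour 1 and 55.5 in tumour 2 against 35364 in epidermis (-6.46 ± 1.37, adjusted p = 0.0141; 0.0771 and 0.0705 without epidermis array 1 and 2). The serpin genes Serpina12 (-6.33 ± 0.72) and Serpinb12 (-6.29 ± 0.56), the zinc transporter gene Slc39a2 (-6.01 ± 0.25) and Btc, an EGF receptor ligand (-5.89 ± 0.32), followed among the 12 largest falls.

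In all, 3015 of 18193 genes were higher and 2267 lower in tumour (limma, Benjamini-Hochberg adjusted p under 0.05; 7345 at an unadjusted p under 0.05), and 1133 and 724 of them by at least 4-fold. Of all calls 57.1% were higher, against 44.6% with quantile normalization (2159 higher, 2685 lower) and 23.7% with each array centred on its median (1463 and 4713). The median gene differed by 0.09 in log2, by -0.19 with quantile normalization and by -0.55 with centring, so differences are relative to the scaling. Camera called 18 of 37 lists, 9 in each direction. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05. By fry 17 were called, but not all the same ones. They included p53 targets, the BCL2 family and Schwann cell markers, which camera did not call. They left out hair shaft (adjusted p by fry = 0.194), skeletal muscle (0.252), cholesterol (0.148) and immediate early genes (0.0751), which camera called. Without epidermis array 1 the counts were 840 higher and 537 lower, and without array 2 they were 965 and 619, where the lone epidermis array is assumed to vary like the tumours. With a tumour left out, the spread comes from the epidermis arrays alone, and the lone tumour is assumed to vary like them. The replicates' median absolute log2 difference was 0.44 for the tumours and 0.27 for epidermis. Calls made above without a tumour array rest on 1 tumour, whose spread may be understated. The median gene differed by 0.12 without tumour 1 and by 0.06 without tumour 2.

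The PDKC1 arrays addressed which genes respond to Hedgehog inhibition in carcinoma cells. With 1 array per time there was no replicate check and no test, and all differences are between single arrays. The direct Hedgehog targets Gli1, Ptch1 and Mycn were lower at both times. Gli1 had an intensity of 841.9 at 0 h, 193.2 at 6 h and 189.6 at 10 h, log2 differences of -2.04 and -2.06 from 0 h. Ptch1 went from 2185 to 686.2 and 549.5 (-1.65 and -1.96), and Mycn from 1047 to 337.8 and 303.8 (-1.59 and -1.73); with the mean of probe sets, Mycn differed by -0.57 at 6 h. Hhip differed by -0.39 at 6 h and -1.54 at 10 h, and the apoptosis inhibitor gene Bcl2 by -0.12 and -0.88. The bright targets Ccnd2, a cyclin gene, and Rab34 differed by -0.13 and -0.27 and by -0.09 and -0.03. Targets at or under 102.9 at 0 h varied in both directions: Pdgfra went from 6.90 to 39.5 and 48.0 (1.28 and 1.48), Sfrp1 from 102.9 to 46.8 and 110.7 (-0.92 and 0.09), Igfbp6 differed by -0.69 and -0.27 and Snai1 by 0.54 and 0.02. The list of 16 targets had a median difference of -0.13 at 6 h and -0.31 at 10 h, lower than all but 8.29% and 0.290% of random lists matched on level.

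Genes of cholesterol synthesis, the pathway controlled by SREBP2, were higher after cyclopamine. Of 18 measured genes 18 were above 0 h at 6 h and 17 at 10 h, with medians of 0.59 and 0.79, higher than in 100% of 10000 random lists at both times. Fdps, farnesyl diphosphate synthase, went from 2935 to 5515 and 8891 (0.91 and 1.59), and Nsdhl from 1433 to 2524 and 3863 (0.81 and 1.42). The lanosterol synthase gene Lss differed by 0.94 and 1.21 and the demethylase gene Cyp51 by 0.81 and 1.26. Mitosis genes lay below most random lists at 6 h and above most at 10 h, with medians of -0.16 and 0.16 (percentiles 0.320 and 98.2). DNA replication genes had -0.14 and 0.05 (percentiles 0.0300 and 87.1), and -0.04 at 6 h with each array centred on its median. Of the 37 lists, only cholesterol and mitosis lay in the lowest or highest 2.5% of random lists at both times. Both times were set against the same 0 h array, so they are not separate checks. Random lists were drawn gene by gene and do not hold genes that move together, so the percentiles are not p-values. Without untreated arrays at 6 h or 10 h, time in culture or handling cannot be told apart from cyclopamine for these lists.

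**Figure D4:**
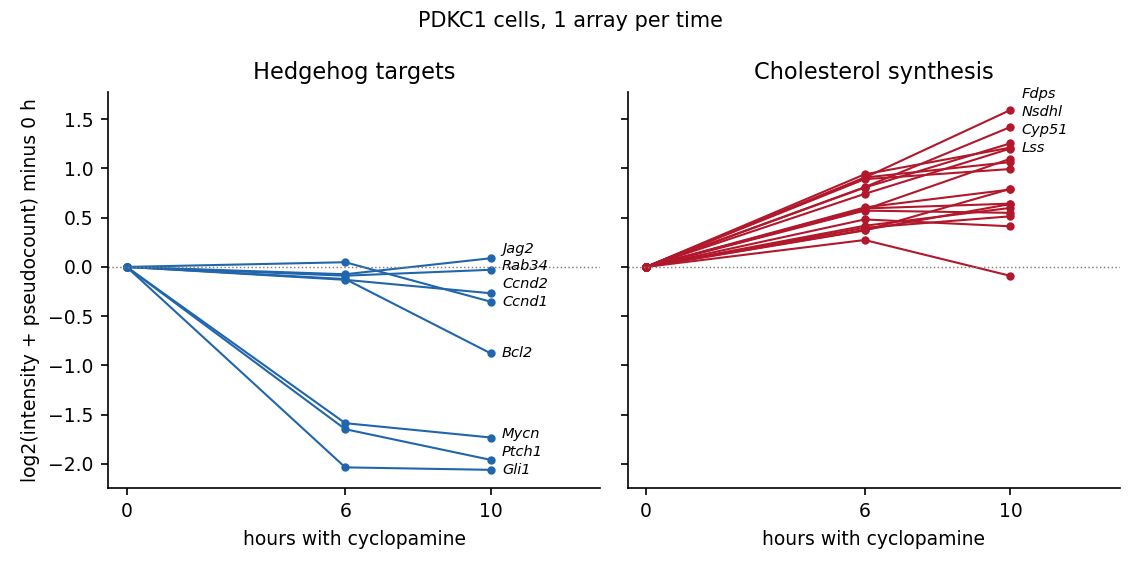
Difference of log2(intensity + pseudocount) from 0 h against hours with cyclopamine in PDKC1, 1 array per time, for Hedgehog targets (left, 8 genes) and cholesterol synthesis genes (right, 17 genes) over the 75th percentile of intensity. Gli1 lay at -2.04 and Mycn at -1.59 at 6 h, and Fdps reached 1.59 at 10 h.

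Over all genes, 117 were at least 2-fold lower than 0 h at both times and 107 at least 2-fold higher, of 11581 whose brightest array was over its median probe set. Counted in the same way, 177 genes set the 6 h array apart from both others and 170 the 10 h array, against 224 for 0 h. With a pseudocount of 64, 31 genes were lower and 9 higher at both times, and with no filter on level 496 and 307. Of the 10 genes with the largest falls Gli1 was the only one over the 75th percentile of intensity; the others, led by Alpk2 (134.0 to 12.2 and 14.4), started between 83.9 and 143.8. The largest rises, led by Icos (2.6 to 67.0 and 94.9), all ended at or under 118.2. Among 6883 genes over the 75th percentile, a filter chosen after the data were seen, 6 were lower at both times: Gli1, Ptch1, Mycn, Calm4, Serpinb1a and St8sia2. Calm4, a calmodulin-like gene of differentiating keratinocytes, went from 887.9 to 244.9 and 106.2. The clock gene Cry1 (288.5 to 626.7 and 645.3) and Oxa1l (239.6 to 507.8 and 546.2) were the 2 higher. Calm4, Cry1 and Oxa1l were named after their values were seen. With this filter 8 genes set the 0 h array apart, 0 the 6 h array and 6 the 10 h array.

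The last comparison asked whether genes higher in tumour were those lower after cyclopamine. Of 2326 tumour-higher genes and 117 genes lower at both times, 13 were shared, where independent lists would share 23.5 and random genes matched on level shared 9 to 22 (percentile 28.2); with the mean of probe sets 6 were shared. Among genes over the 75th percentile, 5 of the 6 lower genes were higher in tumour, against 1.23 from independent lists and 0 to 4 in matched random genes (percentile 99.7). These 5 were Gli1, Ptch1, Mycn, St8sia2 and Serpinb1a, while Calm4 was lower in tumour (-2.02 ± 0.44). St8sia2, a polysialyltransferase gene, differed by 2.93 ± 0.29 between tissues and went from 623.0 to 264.9 and 239.5 in PDKC1. Serpinb1a, an inhibitor of neutrophil proteases, differed by 2.03 ± 0.28 and went from 2265 to 934.1 and 840.6. Among dimmer shared genes, the transporter gene Slco4a1 differed by 3.69 ± 0.31 and went from 447.8 to 96.7 and 151.9, and the proteoglycan gene Vcan differed by 2.56 ± 0.31. The dimmer remainder were Grb14, Pi15, Susd5, Psmb8, Arhgef6 and Epm2a, and 0 h levels of these 6 lay between 78.5 and 299.3.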

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

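The tests of dilution by other cell types, of time in culture, of the change in stromal markers from tumour 1 to tumour 2 and of these markers against matched genes in PDKC1 were chosen only after the result was seen.

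The 3' to 5' ratio of the Actb control probe sets, which no comparison above used as an outcome, was 11.3 in tumour 1 and 93.1 in tumour 2, over the 3.98 and 2.84 of the epidermis. For Gapdh the ratio was 10.6 and 15.4, over 5.27 and 4.52. Of 10092 probe sets with no or several gene names, outside the gene-level tests, 2500 were higher in tumour and 400 lower. Sfrp1 in PDKC1 lay on opposite sides of 0 h at the 2 times, at -0.92 and 0.09, which differ by 1.01; this difference was not tested. The median of the mitosis list likewise went from -0.16 to 0.16, which differ by 0.319, and this difference was not tested.

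Genes of the spinous and granular layers and of barrier lipid synthesis were lower in the tumours, and the tumour RNA had less 5' signal. Dilution of keratinocytes by other cells should lower basal and upper layer genes alike. The basal list's median lay 3.06 above that of the 3 upper layer lists (95% bootstrap interval 2.41 to 3.82). On these 4 arrays the basal and upper layer genes thus did not fall alike. This argues against dilution as the whole cause only if the other cells lack the basal list's genes, which was not tested. The interval, like those below, covers the spread over genes and not between samples. It is too narrow where genes move together, and the estimated correlation was 0.80 for the basal and 0.41 for the granular list. Loss of 5' signal cannot be told apart from lower expression: from tumour 1 to tumour 2 the 32 called members changed by -1.20 relative to all genes (-1.48 to -0.479). The predicted fall was scaled from these members' own difference from epidermis, -3.18 relative to all genes, as if the loss caused all of it. By the rise of the control ratios between the tumours it was -2.97 for Actb and -1.24 for Gapdh. The members were chosen as lower, so the prediction is not independent of them. The bounds, a part of each set by choice, were -1.48 and -0.618. The prediction written beforehand named only Actb, whose bound of -1.4845 lay just outside the interval's end of -1.4833. That criterion against the loss was thus met by a very small margin. The Gapdh bound lay within the interval, so the control genes leave this cause undecided. In tumour 1 alone these members lay at -2.67 from epidermis relative to all genes (-3.51 to -2.02). There the log2 ratio of 3' to 5' signal was above epidermis by 1.74 for Actb and 1.12 for Gapdh. These values rest on 1 tumour array and on members chosen as lower, so they decide nothing. A biological difference between carcinoma and newborn epidermis, in tissue and age, stays open and was not tested.

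Called fibroblast, endothelial, mast cell and muscle markers were higher in the tumours. From tumour 1 to tumour 2 the 27 members changed by -0.20 relative to all genes (-0.35 to 0.31), and by -0.11 without muscle (-0.32 to 0.34). The bounds for loss of 5' signal were 1.11 by Actb and 0.46 by Gapdh, each a chosen part of the predicted rise. That rise was likewise scaled from the members' own difference from epidermis, 2.38 relative to all genes, as if the loss caused all of it. The change stayed under both bounds, but this cannot exclude the loss. The 2 tumours may also differ in how much stroma they hold, which could hide a rise. Muscle members changed by -2.26, endothelial members by -0.32 and fibroblast and matrix members by 0.32. For the 14 fibroblast and matrix members alone, loss of 5' signal cannot be told apart either (-0.25 to 0.55), since the Gapdh bound of 0.46 lies within the interval. The 3 to 5 members of each other list were too few to weigh. The median in tumour 1, 2.63 above epidermis (2.34 to 3.26) and past the bound of 1 set beforehand, decides nothing, because that tumour had an Actb ratio of 11.3 itself and members were chosen as higher. Dermis, vessels and muscle in the dissected tumours may account for these higher markers. The 27 called members lay at a median of -4.39 in PDKC1 at 0 h relative to the tumours (-5.38 to -2.13). Other genes chosen as higher, matched on level and difference, lay at -2.80 to -1.44. All 49 measured members of the 4 lists, called or not, lay at -1.995 (-3.557 to -1.485), without a matched set. PDKC1 at 0 h also differed from the tumours in RNA input and in Actb ratio, 1.15 against 11.3 and 93.1. Such markers may be low in a cell line whatever the tumours held, so this contrast leaves the cause open. The abundant matrix genes Col1a2 and Col3a1 had intensities of 19093 and 22487 in tumour 1. Vim, Sparc, Col5a1 and Eng were the called members not at least 2-fold lower in PDKC1. Of these, Vim (0.995) and Sparc (0.844) were higher in PDKC1 at 0 h than in the tumours. How much stroma belongs to the tumour itself was not tested.

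The Hedgehog targets Gli1, Ptch1 and Mycn were lower in PDKC1 at both times. A difference between single arrays cannot be told apart from a response for the list as a whole: its higher percentile among matched random lists was 8.29, at 6 h, where under 2.5 was needed at both times. Time in culture or handling cannot be told apart from cyclopamine either, because 0 untreated arrays at 6 h or 10 h exist in the design. Among genes over the 75th percentile, 3 of 8 targets were among the 6 lower genes, where independent lists would share 0.00697. An effect of blocked Hedgehog signalling stays open as a hypothesis.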

How the results depend on the processing

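The filters at the 75th percentile of intensity were chosen after the data were seen. Among the named genes and the gene lists, no called direction reversed under the alternatives computed for them. Single probe sets did part: of 3206 called genes with several probe sets, 228 had a probe set called the opposite way. Named genes of the tissue comparison kept their side of the threshold in 1596 combinations of gene and alternative, lost the call in 203 and gained it in 6; gene lists kept it in 442, lost it in 25 and gained it in 14. In PDKC1, 350 values of named genes moved by under 1 log2 unit and 46 by more; 362 medians of lists moved by less than the half-width of the central 95% of random lists and 8 by more. Most lost gene calls came from leaving out an epidermis array (58 and 54 of 142), because the lone epidermis array is then assumed to vary like the tumours. Signal over background limits genes near the pseudocount of 16. Simulated 2-fold changes were not called, but far fewer genes were changed there than were called in the data. Of the 3015 higher and 2267 lower calls in the data, 2690 and 1950 were at least 2-fold, so smaller differences were called too.

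In the tissue comparison, 3015 genes were higher and 2267 lower. With each array centred on its median 1463 were higher and 4713 lower, where the median of all genes went from 0.09 to -0.55. With all probe sets 8255 and 4132 were called, where more features were tested. Leaving out 1 array gave 840 to 3553 higher, 537 to 3353 lower, and 17 to 22 lists called. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05. With the replicate number as a block, called the replicate block, 2893 were higher and 2224 lower. The numbers do not pair the arrays: over genes, replicate 1 minus replicate 2 correlated between tissues at r = -0.000636 (Spearman's rho -0.0157).

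In PDKC1 117 genes were lower and 107 higher at both times. With a pseudocount of 64 they were 31 and 9, and with 4 the higher were 161, where the pseudocount sets the size of changes in dim genes. The mean of probe sets gave 75 lower; the cause was not tested. At 1.5-fold there were 327 and 296, with no level filter 496 and 307, and over the 75th percentile 6 and 2, where the threshold or the genes admitted differ. The 13 shared genes became 6 with the mean of probe sets (the cause was not tested), 49 at 1.5-fold, 40 with no level filter and 5 over the 75th percentile.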

Other observations

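The gene families described here were chosen after the data were seen, and each is given as counts with no test of the family. Of 42 collagen genes 29 were higher in tumour and the median log2 difference was 1.94 (1.49 with quantile normalization and 1.30 with each array centred on its median). They included the basement membrane collagen gene Col4a4 (4.44 ± 0.57), the cartilage collagen gene Col9a3 (4.13 ± 0.42) and Col6a2 (3.92 ± 0.32). Of 48 keratin genes 15 were lower and 4 higher, with a median of -0.73. With quantile normalization 16 were lower and 3 higher (median -0.83), and with centring 25 were lower and 2 higher (-1.37). Krt23 differed by -5.75 ± 0.67, Krt78 by -5.13 ± 0.51 and Krt77 by -3.60 ± 0.38, while Krt24 differed by 4.28 ± 0.68. Of 20 kallikrein proteases, which shed the outer epidermis, 8 were lower, including Klk8 (-5.39 ± 0.34) and Klk9 (-3.89 ± 0.32), and 8 and 9 with these scalings. Of 18 clade B serpins, their inhibitors among others, 8 were lower and 2 higher (7 and 1, then 8 and 1, with these scalings).

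Desmosomal cadherins differed by member: Dsc1 (-2.31 ± 0.42) and Dsg1b (-1.83 ± 0.32) of the upper epidermis were lower, and Dsc2 (1.77 ± 0.29) and Dsg2 (0.74 ± 0.22) were higher; with each array centred on its median 1 of the 6 was called higher. Of 20 claudin genes, which form tight junctions, 3 were lower: Cldn23 (-5.28 ± 0.41), Cldn4 (-4.38 ± 0.51) and Cldn1 (-0.82 ± 0.23); 2 were lower with quantile normalization and 5 with centring. Of 19 Wnt ligand genes 4 were lower, including Wnt4 (-2.12 ± 0.31), and 4 and 7 with these scalings. Of 33 Hox genes 6 were lower, led by Hoxc4 (-3.37 ± 0.44), and 2 were higher; with quantile normalization 9 were lower and with centring 11, and with neither were the 2 called. Of 20 aldehyde dehydrogenase genes 5 were higher, led by Aldh3a1 (2.52 ± 0.55), and 3 lower; 3 were higher and 3 lower with quantile normalization, and 3 higher and 6 lower with centring. Among probe sets left out of the gene-level tests, the one assigned to both H19, an imprinted noncoding RNA, and the microRNA gene within it had a log2 difference of -7.72 ± 0.27 (adjusted p = 0.000214).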
